A study of Homo sapiens with 10 samples.

How the data were processed

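The series holds 10 poly(A) RNA-seq libraries of HEK293T cells in 5 groups of 2, VP64, VPR, SAM, Suntag and a guide-only control, and the group and replicate number were taken from the sample titles. Per the labels' protocols, cells were transfected with a lipid reagent, RNA was column-purified, poly(A)-selected and DNase-treated, first strands were primed with random hexamers, and libraries were made by tagmentation, a preparation that does not mark the strand. Overlapping and antisense genes can therefore not be told apart.

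The authors deposited 1 table per library. Per the submitters' processing notes these came from RSEM 1.2.1 with the hg19 build, and the transcript annotation is not given in the sources used here. Per the file headers, each table gives for 31848 gene clusters the expected count, which is RSEM's estimated count and need not be whole because a read that fits several transcripts is divided between them. The deposited TPM values are RSEM's abundances of transcripts scaled to a fixed library sum, adjusted by effective length within each library. Per the file headers, the authors' tables also give a transcript length and an effective length. In RSEM the latter is about the transcript length less the mean fragment length, which was derived here from their difference. The deposited FPKM column was not used. Totals ran from 3316534 to 7447949 expected counts per library. The most abundant cluster took 7.51% to 9.63% of the counts.

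The clusters carry 82960 transcript identifiers, and 4 of them were found in the gene name tables at hand, which use a later genome build. The files do not pair identifiers with names. HBG1, its near-identical copy HBG2, the component genes of the activators and the 18 gene lists fixed before the data were examined were therefore not tested, and neither were the gene set tests. The rule for named genes, also fixed then, takes called genes with a mean of at least 1 CPM that changed the same way in every library, ranked by size of change. Since names are lacking, at most 2 clusters called higher and 2 called lower are identified by number. Against the control, the ranking is led by cluster 4232 among higher and 9955 among lower clusters in SAM, and by 10140 among lower clusters in VP64. Clusters 9955, 10140 and 29063 were also summed with clusters next in the list or of nearly equal length, which may share their reads, chosen after their values were seen. Other clusters lead the lower calls in VPR and Suntag and are not identified here. Cluster 29063 was chosen after its values were seen.

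Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, which kept 13241 clusters, TMM factors, and the quasi-likelihood F test in 1 fit of all 10 libraries with a coefficient per group and 5 residual degrees of freedom, so that groups of 2 share an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method within each of 10 comparisons, with a threshold of 0.05. The fit over all groups was chosen before the data were examined. SE of a log2 change is its size divided by the square root of F. A two-sided permutation of 2 libraries against 2 cannot give a p below 0.333, so single comparisons rest on this model.

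Ratios of counts were taken from counts and library totals summed over a group, with exact 95% intervals for the ratio of Poisson rates. A group with 0 counts was set to a floor of 3 counts over the group, and the result is given as a bound. CPM values of single clusters are scaled by the library's summed expected counts. A count was called whole within 0.01. Whole counts in all 10 libraries were found for 2691 of the 13241 tested clusters, and for 42 of the 86 clusters called at least 2-fold in SAM against the control. The rest had counts that were not whole, as reads divided between clusters would give, and the cause was not tested.

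The test was checked on simulated data with the spread of the real libraries and a known set of changed clusters in VPR against the control. Of 12988 clusters tested there, it called 56.7% of 67 changed 1.5-fold, 76.1% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, all in the right direction, and made 20 false calls beside 151 true ones. False calls were thus 11.7% of calls in this simulation, above the threshold of 0.05, so the counts of calls printed may hold more false ones than that threshold states. Shared controls were covered by 20 simulations of unchanged groups. Correlations across libraries used 100000 permutations.

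The alternatives fixed before the data were examined were RLE factors, DESeq2 1.42.0, no filter on low counts, a fit of the compared groups alone, the replicate number as a block, each library left out in turn, a minimum of 2-fold, and for similarity another pseudocount and a minimum TPM of 1. An offset of RSEM's effective length and the removal of each library's loess trend on transcript length were added after seeing the data.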

Results

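Poly(A) RNA was sequenced from HEK293T cells, a human embryonic kidney line, after transfection with a guide RNA against HBG1, a fetal globin gene, and 1 of 4 activators built on catalytically dead Cas9. VP64 is an activation domain of viral origin. VPR fuses VP64 to p65 and Rta activation domains, SAM recruits activation domains through RNA hairpins in the guide, and Suntag recruits copies of VP64 through a peptide array. A control group was labelled as guide only. Each of the 5 groups held 2 libraries, 10 in all. The labels do not say whether these came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

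The expected counts of a library summed to 5351863 and 3316534 in VP64, 5049833 and 7447949 in VPR, 3434486 and 4435296 in SAM, 5734411 and 5580553 in Suntag, and 4659135 and 6072335 in the guide-only control. The files list 31848 gene clusters by number with their transcript identifiers and do not pair these with gene names. HBG1 was therefore not located, and clusters are described by number, transcript length and counts. Of these clusters, 13241 had enough counts to be tested, and they held about 99.8% of the counts of every library. The 2 libraries of each group differed beyond sampling noise, with a chi-square per cluster from 1.70 in VP64 to 6.14 in Suntag.

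Across all 31848 clusters the correlation of mean log2(TPM + 1) with the control was 0.9954 for VP64, 0.995 for VPR, 0.9936 for SAM and 0.9957 for Suntag. These are correlations across clusters, which are not independent replicates. Between the 2 libraries of a group the same correlation ran from 0.9905 in SAM to 0.9938 in VPR. The former compare means of 2 libraries, which carry less noise than single libraries, and values this near 1 do not separate the activators. On principal components of log2 CPM, the first component held 21.5% of the variance and placed the SAM libraries at 35.9 and 24.4.

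Cluster 4232, with 4 transcripts, gave the clearest contrast between activators, and the question it bears on is how strongly each activator raised single transcripts. It held 260 and 295 counts in the SAM libraries, 88 and 75 in VPR, 106 and 73 in Suntag, 0 and 0 in VP64, and 0 and 3 in the guide-only control. These counts were whole in all 10 libraries. The level was 71.1 ± 6.50 CPM in SAM, 13.8 ± 5.20 CPM in VPR and 15.8 ± 3.82 CPM in Suntag (SD, n = 2 each). From summed counts against the 3 counts of the control, SAM was 252-fold higher (95% exact interval 85.9 to 1230), Suntag 56.6-fold (19.1 to 277) and VPR 46.7-fold (15.7 to 229). All 3 rises passed edgeR's quasi-likelihood test, with adjusted p = 1.96e-07 for SAM, 0.000743 for Suntag and 0.000327 for VPR, in 2 of 2 libraries each. VP64 had no counts, which allows up to 0.346 CPM, and no fold against the control is given because both groups lay at or under the floor of 3 counts per group. Intervals and floors cover counting error only. The 3 control counts all came from replicate 2, and the fitted log2 change was 11.40 for SAM, 9.30 for Suntag and 9.10 for VPR without that library, values against 0 counts that are no measure of size. Without control replicate 1 it was 7.07, 4.97 and 4.76, and all 3 calls held in both fits.

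**Figure D1:**
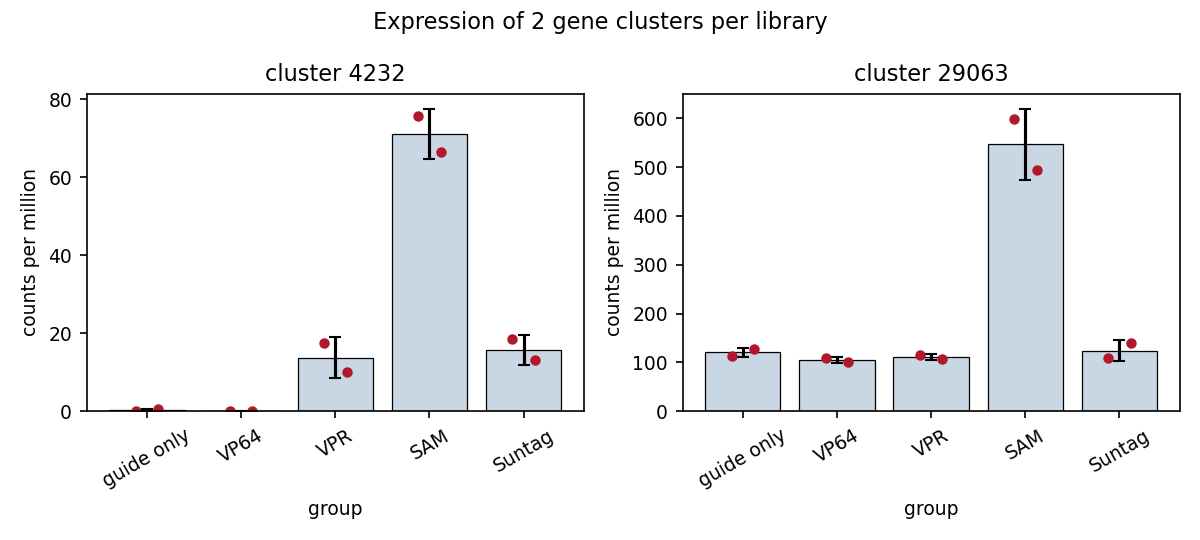
CPM (y axis) of clusters 4232 and 29063 in the 5 groups (x axis); bars are means of 2 libraries, error bars SD, and points single libraries. Cluster 4232 lay at 71.1 CPM in SAM, at 13.8 and 15.8 CPM in VPR and Suntag and at or near 0 in VP64 and the control, and cluster 29063 was raised in SAM.

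The activators were also compared with each other on this cluster. SAM exceeded Suntag 4.46-fold (95% exact interval 3.76 to 5.31, edgeR adjusted p = 0.000513), and VPR stood at 0.185 of SAM (0.154 to 0.221, edgeR adjusted p = 0.000189). VPR and Suntag did not differ by the test, with VPR at 0.824 of Suntag (0.663 to 1.03, edgeR adjusted p = 0.775). Against a floor of 3 counts over the VP64 group, SAM was at least 204-fold, Suntag at least 45.7-fold and VPR at least 37.7-fold higher than VP64. Without VP64 replicate 1 the calls of VPR and Suntag against VP64 ended, at edgeR adjusted p = 0.0867 and 0.138, while the fitted log2 differences were 9.13 with and without that library for VPR, and 9.34 and 9.33 for Suntag. The remaining VP64 library held 0 counts as well.

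SAM changed 689 clusters against the guide-only control, 300 higher and 389 lower, and 86 of them by at least 2-fold, of which 73 were higher. The median log2 change was 0.63 among higher and -0.49 among lower clusters. Some of the rises rested on few counts. The cluster ranked 2 among higher ones by the rule for named genes held 34 summed counts in SAM and 3 in the control. Its ratio was 15.5 (95% exact interval 4.86 to 78.6). Cluster 29063, of 2 transcripts, with counts that are not whole and singled out after its values were seen, rose from 121 ± 9.85 CPM in the control to 547 ± 73.2 CPM in SAM (SD, n = 2 each). This was a log2 change of 2.15 ± 0.11 (SE, edgeR adjusted p = 5.9e-08). It was higher in SAM than in VP64, VPR and Suntag as well, with log2 differences of 2.29, 2.19 and 2.07 and edgeR adjusted p = 3.61e-08, 4.36e-08 and 9.06e-08. Its log2 change against the control was -0.14 in VP64, -0.04 in VPR and 0.08 in Suntag, none of which passed the test. Summed with the next cluster in the list, whose counts are not whole either, the level was 154 ± 8.41 CPM in the control and 576 ± 67.7 CPM in SAM (SD, n = 2 each). These sums lay up to 0.22 from a whole number, so that further clusters may share some of the reads. Cluster 9955 was called lower in SAM, with 0 counts in both SAM libraries and 57 in the control (edgeR adjusted p = 0.0011), but its counts are not whole. The next cluster in the list moved the other way, with 57 counts in SAM and 10 in the control (log2 change 2.86, edgeR adjusted p = 0.0226), and the sums of this pair lay within 0.02 of a whole number in all 10 libraries. Summed over the pair, the level was 7.21 ± 0.32 CPM in SAM and 6.29 ± 0.513 CPM in the control (SD, n = 2 each), a ratio of 1.16 (95% exact interval 0.8 to 1.68), so no fall in level was detectable. The calls of cluster 9955 against other activators ended in some fits without 1 library: against VP64 without SAM replicate 1 or 2 (edgeR adjusted p = 0.0867 and 0.0906) or VP64 replicate 1 or 2 (0.113 and 0.0537), against Suntag without SAM replicate 1 or 2 (0.114 and 0.0846), and against VPR without SAM replicate 1 (0.0555). Leaving out 1 library moved the SAM count between 60, without SAM replicate 1, and 1047, without Suntag replicate 2. DESeq2 called 331 clusters, 100 higher and 231 lower.

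With all 10 libraries in the fit, more clusters separated SAM from the other activators than separated these from each other. By edgeR, 568 clusters separated SAM from VP64 (201 higher, 367 lower in SAM), 752 separated VPR from SAM (472 higher, 280 lower in VPR) and 228 separated SAM from Suntag (95 higher, 133 lower in SAM). At least 2-fold the balance was the opposite in each, with 47 higher and 15 lower in SAM than in VP64, 12 higher and 65 lower in VPR than in SAM, and 34 higher and 6 lower in SAM than in Suntag. By contrast, 1 cluster, 4232, separated VPR from VP64, 31 separated Suntag from VP64 (16 higher, 15 lower in Suntag), and 0 separated VPR from Suntag. At an unadjusted p under 0.05 the numbers for these pairs were 1144, 1957 and 1761, and DESeq2 called 11 (4 higher, 7 lower), 125 (60 and 65) and 61 (48 and 13). In SAM, 31 clusters were higher and 42 lower than in each of the other 4 groups. The counts for the pairs depended on single libraries, and their order changed without SAM replicate 1. Without SAM replicate 1 there were 27 calls for SAM against VP64, 9 for VPR against SAM and 3 for SAM against Suntag, and 29 for Suntag against VP64. SAM against VP64 and Suntag against VP64 both had their fewest calls without VP64 replicate 1, with more for SAM. VPR against Suntag and Suntag against VP64 had their most calls without Suntag replicate 1. In that fit VPR against SAM and SAM against Suntag also had their most calls, and more than those pairs. DESeq2's split was 75 higher and 263 lower for SAM against VP64, 342 and 75 for VPR against SAM, and 55 and 179 for SAM against Suntag. Calls of VPR against SAM also varied with transcript length, with medians of 1719 nt among clusters higher in VPR and 4719 nt among lower ones. Of clusters under 700 nt, 13.7% were called higher in VPR and 0.403% lower. Removing the length trend lowered the number of calls for this pair, so part of the separation may go with length.

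VPR changed 874 clusters against the guide-only control, with 607 higher and 267 lower. Most changes were small, with a median log2 change of 0.52 among higher and -0.43 among lower clusters, and 28 reached 2-fold, 22 of them higher. Of the 607 higher clusters, 91 had a transcript length under 700 nt and 320 one of 700 to 1500 nt. Of 248 tested clusters under 700 nt, 36.7% were called higher and 0 lower, and of 6260 over 3000 nt, 0.447% were higher and 3.87% lower. The median transcript length was 1164 nt among higher clusters and 5557 nt among lower ones, against 2871 nt over all tested. With the trend of each library with transcript length removed, an alternative chosen after seeing the data, SAM had 677 calls, of which 580 were among its 689. VPR then had 86 calls (61 higher, 25 lower), of which 72 were among the 874. Leaving out 1 library moved the count between 143, without VPR replicate 1, and 1332, without Suntag replicate 2. Without VPR replicate 1, SAM had 638.

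VP64 changed 108 clusters against the control, 88 higher and 20 lower, and 9 of them by at least 2-fold (5 higher, 4 lower). Suntag changed 176, with 131 higher and 45 lower, and 15 by at least 2-fold (7 higher, 8 lower). In both groups, higher clusters again had short transcripts, with median lengths of 910 nt in VP64 and 1097 nt in Suntag, and 9.27% of clusters under 700 nt were called higher in each. A cluster of 1 transcript of 301 nt rose 6.49-fold in VP64 (236 against 45 summed counts, 95% exact interval 4.70 to 9.14) and was the single cluster called at least 4-fold higher in all 4 activators. Its counts were not whole, and a second cluster of 301 nt moved with it, so its level is uncertain where reads fit both. Cluster 10140, of 6806 nt, held 0 counts in VP64, VPR and Suntag, 47 in SAM and 53 in the control, and was called lower in the former 3 groups (edgeR adjusted p = 0.0308, 0.00485 and 0.0197). Its counts are not whole, and a pair of clusters of 6807 nt with equal counts was called higher in the same groups, with log2 changes of 2.38 in VP64, 1.91 in VPR and 2.31 in Suntag (edgeR adjusted p = 0.0383, 0.0318 and 0.0316). Summed over these 3 clusters there were 67 counts in VP64, 67 in VPR, 66 in SAM, 83 in Suntag and 71 in the control. The ratios to the control were 1.17 (95% exact interval 0.824 to 1.65) in VP64, 0.81 (0.572 to 1.15) in VPR and 1.11 (0.798 to 1.54) in Suntag, so no fall of the sum was detectable. These sums lay up to 0.4 from a whole number, so that further clusters may share some of the reads and the summed level too is uncertain. Without control replicate 2 none of the calls of cluster 10140 stood, at edgeR adjusted p = 0.237, 0.0573 and 0.174, and that in VP64 also ended without VP64 replicate 1 (0.302) or 2 (0.2). With the length trend removed, VP64 had 19 calls and Suntag 14, 7 of them higher. No cluster was called for VP64 without either of its libraries, and Suntag had 7 calls without control replicate 2.

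**Figure D2:**
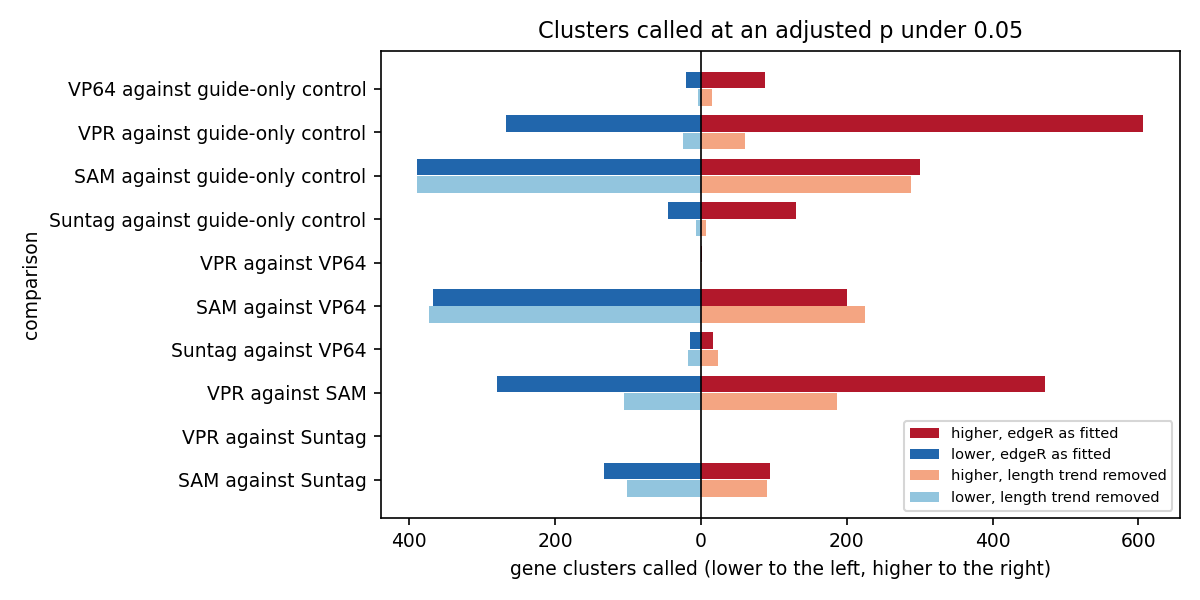
Number of gene clusters called at an edgeR adjusted p under 0.05 (x axis, lower to the left and higher to the right) in the 10 comparisons (y axis), as fitted (dark bars) and with the transcript length trend removed (pale bars). VPR against the control fell from 874 to 86 calls, while SAM against the control had 689 and 677, with 580 in both.

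The shift with transcript length was seen in every activator group, each compared with the same control libraries, so these are not independent observations. The median log2 change of clusters under 700 nt against the control was 0.48 in VPR, 0.38 in VP64, 0.26 in Suntag and 0.23 in SAM, and that of clusters over 3000 nt was -0.13, -0.05, -0.07 and -0.03. Per library, the median deviation of short minus long clusters was -0.32 ± 0.02 log2 units in the control and 0.29 ± 0.10 in VPR, 0.12 ± 0.01 in VP64, 0.02 ± 0.17 in Suntag and -0.10 ± 0.14 in SAM (SD, n = 2 each). Both control libraries lay below all 8 activator libraries, on a measure built after the pattern was seen. The mean fragment length derived from transcript and effective lengths was 132 ± 2.51 nt in the control and shorter in the activator groups. It was 114 ± 13.9 nt in VP64, 113 ± 1.46 nt in VPR, 108 ± 13.1 nt in SAM and 94.2 ± 4.82 nt in Suntag.

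**Figure D3:**
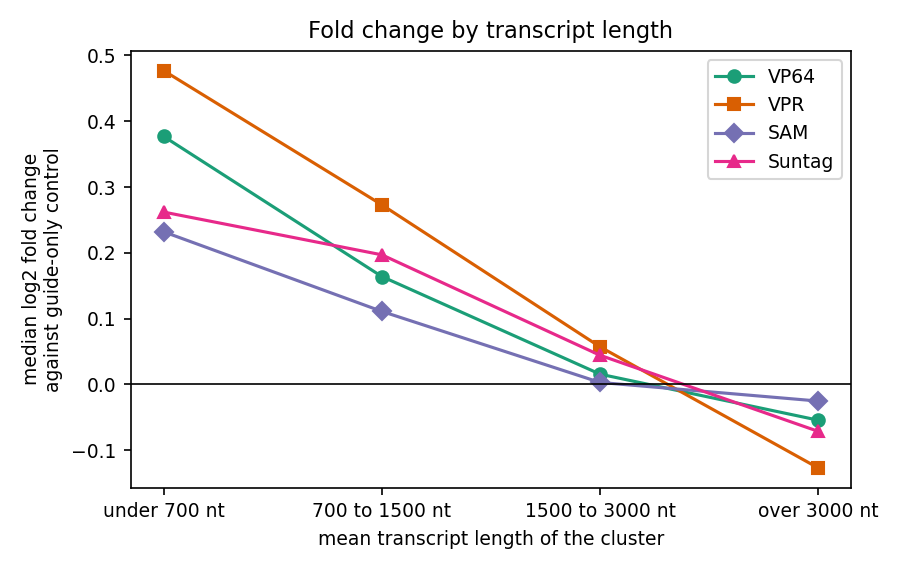
Median log2 fold change against the guide-only control (y axis) of tested clusters in 4 classes of mean transcript length (x axis), for the 4 activators (lines). Short clusters lay above 0 and clusters over 3000 nt below 0 in each activator, from 0.48 to -0.13 in VPR.

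Calls were shared between activators. Against the same control libraries, 322 clusters were called in the same direction in at least 2 activators, 57 higher and 13 lower in at least 3, and 12 higher in all 4. In 20 simulations of unchanged groups against the shared controls the mean number in at least 2 was 0.85, but these simulations made only 6.35 calls on average over the 4 comparisons, so few could be shared and the value is no measure of chance for lists as long as those observed. VPR and SAM shared 104 higher and 59 lower clusters, where independent lists would share 13.8 and 7.84, and VPR and VP64 shared 84 and 15, against 4.03 and 0.403. Over the 6 pairs of activators the covariance of log2 changes ran from 0.0751 to 0.119, and from 0.0349 to 0.0358 in the simulations. Their correlation across clusters ran from 0.352 to 0.56, and from 0.451 to 0.511 in the simulations, and 3 of the 6 pairs lay below their simulated value. The simulated groups had the same mean level of each cluster and no length trend, so their log2 changes spread less. The higher covariance is therefore no measure of sharing beyond the controls. The numbers for independent lists take no account of the shared controls either. The 2 control libraries were not split between activators, so part of the sharing may come from them. No group was labelled as dead Cas9 without an activation domain, so what the activators have in common beside their domains was not tested. With the length trend removed, 48 clusters were shared by at least 2 activators.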

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

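The tests on clusters 4232 and 29063 were chosen only after their values were seen, and those on transcript length were set after the length pattern was seen but before their outcomes. A difference between groups, tested by edgeR, drew attention to 12 clusters in which SAM differed by at least 2-fold from each other group. The smallest log2 difference of SAM from another activator was 2.10 for cluster 4232, 2.07 for cluster 29063, and 1.04, 1.24, 1.25, 1.43, 1.71, 2.24, 2.32, 2.54 and 2.76 for 9 others that were higher. It was -6.53 for cluster 9955, a fitted value against 0 counts in SAM. Summed with the next cluster in the list, the level was 7.21 ± 0.32 CPM in SAM and 4.63 ± 0.582 CPM in VP64 (SD, n = 2 each). Of the 9 others, the 1 at 2.76 had counts that were not whole, with 47 summed counts in SAM and 10 in VPR. None of the 9 was summed with further clusters, so shared reads may affect their differences too.

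Cluster 4232 was high in VPR, SAM and Suntag and at or near 0 in VP64 and the control. If 1 library were mislabelled between groups at different levels, the 2 libraries of a pair would differ, which the counts argue against. The highest ratio of CPM between the 2 libraries of VPR, SAM or Suntag was 1.73, and no VP64 or control library held more than 3 counts. The cluster cannot show a swap between VPR and Suntag or between VP64 and the control, whose levels were alike. Nor can it show a swap of whole pairs. That the cluster is the guide's target is a candidate explanation that could not be settled, since no table names it. Clusters called at least 4-fold higher in at least 3 activators numbered 2, this one and one of 301 nt that also rose in VP64, and this leaves the guide's target open.

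Cluster 29063 was higher in SAM than in each other group. A technical explanation is that reads of the transfected SAM sequences, which carry human protein domains, were counted as the cell's own transcripts. If so, a human domain that SAM carries and VPR lacks could raise a cluster in SAM alone, the pattern of cluster 29063. Part of HSF1 is such a domain, and whether the cluster is HSF1 is not known without a name. A sequence shared by VPR and SAM could raise another cluster in both. The number of other clusters higher in VPR and in SAM than in VP64, Suntag and the control was 0. This count decides nothing, since VPR against Suntag had 0 calls in all. Induction of the cell's own gene cannot be told apart from reads of the transfected sequences without the reads themselves.

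Short transcripts were higher against long ones in activator libraries than in the control. Total count as the cause was argued against, since the control totals of 4659135 and 6072335 lie within the activator range of 3316534 to 7447949, and by a correlation of 0.191 with the short-minus-long value over 10 libraries (permutation p = 0.6, adjusted over 2 relations 0.6; Spearman's rho 0.127, p = 0.73; 0.12 without the 2 most extreme libraries). Effective length alone was argued against as well, since 79.0% of the difference was left after division by it (76.4% to 81.9% with each library left out). Fragment length remains open, with a correlation of -0.409 (permutation p = 0.24, adjusted 0.48; Spearman's rho -0.406, p = 0.25; -0.431 without the 2 most extreme libraries), and in 2 of 5 replicate pairs the library with shorter fragments had the higher value. It may not be separable from the presence of an activator, because both control libraries had the longest fragments, and an effect of the activators themselves was not tested.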

How the results depend on the processing

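The length alternatives were chosen after seeing the data. Counts of calls depended strongly on the setting, and the causes were not tested unless stated. Under RLE factors all 10 counts stayed within 1.5 times. With no filter they rose to 533 (VP64), 1388 (VPR), 1280 (SAM) and 590 (Suntag) against the control, and to 83 (VPR against VP64), 1213 (SAM against VP64), 529 (Suntag against VP64), 1444 (VPR against SAM), 402 (VPR against Suntag) and 857 (SAM against Suntag). With only the groups compared they were 617 (VP64), 1154 (SAM) and 24 (Suntag) against the control, and 39, 1594, 49, 14 and 61 for VPR, SAM and Suntag against VP64 and VPR and SAM against Suntag. DESeq2 gave 163 (VP64) and 331 (SAM) against the control, and 11, 338, 125, 417 and 61 for VPR, SAM and Suntag against VP64, VPR against SAM and VPR against Suntag. DESeq2 gave no adjusted p for cluster 4232 in any comparison, and its unadjusted p for SAM against the control was 1.25e-19. At least 2-fold left 9, 28, 86 and 15 against the control, and 62, 3, 77 and 40 for SAM and Suntag against VP64, VPR against SAM and SAM against Suntag.

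The effective length offset gave 44, 580, 450 and 53 calls against the control, 17 for Suntag against VP64, 134 for SAM against Suntag, and 139 clusters shared by at least 2 activators. The removed length trend gave 19 (VP64), 86 (VPR) and 14 (Suntag), 293 for VPR against SAM and 48 shared clusters, while SAM against the control had 677. Similarity to the control was 0.9902, 0.9908, 0.9873 and 0.9905 for VP64, VPR, SAM and Suntag with log2(TPM + 0.1), and 0.9889, 0.9876, 0.9839 and 0.9894 over clusters with a mean TPM of at least 1.

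Replicate numbers did not pair the libraries: deviations of replicate 1 correlated between -0.067 and 0.062, with 0 of 10 pairs over 0.1. With the replicate block there were 68 (VP64) and 108 (Suntag) calls against the control, 1 for VPR against Suntag and 149 for SAM against Suntag, and the other counts stayed within 1.5 times.

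With each library left out in turn, a lone library was assumed to vary like the other groups. For VP64 against the control the count ran from 0, without either VP64 library, to 362 without Suntag replicate 1, for VPR from 143 to 1332, for SAM from 60 to 1047, and for Suntag from 7 without control replicate 2 to 376 without Suntag replicate 1. The ranges were 1 to 3 for VPR against VP64, 12 to 936 for SAM against VP64, 0 to 528 for Suntag against VP64, 9 to 1186 for VPR against SAM, 0 to 476 for VPR against Suntag and 3 to 622 for SAM against Suntag. Without control replicate 1 or 2, counts fell to 32 and 3 (VP64), 244 and 178 (VPR), 135 and 170 (SAM), and 23 and 7 (Suntag). Over all alternatives and comparisons, 26 signs of called clusters turned, 25 of them for VPR against the control with the length trend removed, and 0 of these were called in the other direction. With a library left out, the larger of the higher and lower counts changed for VPR against VP64 (0 higher and 1 lower without VP64 replicate 1, 1 and 2 without either VPR library), for SAM against Suntag (2 and 1 without SAM replicate 1) and for Suntag against VP64 (245 and 283 without Suntag replicate 1, 16 and 20 without either control library). It also changed for VPR against VP64 with no filter (30 and 53), with only the groups compared (11 and 28) and by DESeq2 (4 and 7), and for Suntag against VP64 with only the groups compared (24 and 25), the effective length offset (8 and 9) and DESeq2 (60 and 65). At least 2-fold, the larger count changed for SAM against the control (73 higher and 13 lower), VP64 (47 and 15) and Suntag (34 and 6), for VPR against SAM (12 and 65) and for Suntag against the control (7 and 8). Of the clusters identified by number, the call of cluster 10140 in VP64, where a pair of nearly equal length rose, ended with the replicate block (edgeR adjusted p = 0.0523), the effective length offset (0.0533) and the removed length trend (0.067), and that in Suntag with the last (0.0517), all at similar fold changes. The comparisons with HBG1 and HBG2, their summed counts and the gene set tests were not run. Depth limits clusters with few counts, where 0 in a group allows 0.24 to 0.381 CPM.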

Other observations

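One cluster held 29.5 and 22.5 counts in the Suntag libraries and 0 in all 8 others, and passed edgeR's test for Suntag against the control at adjusted p = 0.0166. A second cluster held the same 29.5 and 22.5 counts in those libraries and 39.4 to 70.1 in the others. Summed over this pair, the level was 9.18 ± 1.57 CPM in Suntag and 8.75 ± 1.89 CPM in the control (SD, n = 2 each), and equal counts are what an even division of shared reads between a pair of copies gives.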
